A study of Haloferax volcanii DS2 with 12 samples.

How the data were processed

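RNA sequencing was carried out on total RNA from cultures of the halophilic archaeon Haloferax volcanii. Per the labels' protocols, RNA was extracted with a commercial kit and directional Illumina libraries were prepared from it. The submitters' processing notes name fastp, a read trimmer, and Bowtie2, a read aligner, without versions. The read counter, the genome build and the annotation are not given in the sources used here.

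The authors deposited 1 table for the whole series, which by its name holds TPM values for 3901 genes in 12 value columns. TPM divides each gene's reads by gene length and scales every library to the same total, so it keeps no sequencing depth, and the depth per sample is unknown. The value columns carry serial names only. None of these names occurs in the labels of the 12 samples (0 of 12 columns matched), so no column was assigned to a sample, a strain or a dose. Assignment by column order or by the measured values, including those of the deleted gene, was not used. This was a choice to take groups from the labels alone. The value columns were inspected for their scale, their most abundant genes, the deleted gene with its neighbours and the correlations between columns, and this inspection entered no result. All 12 value columns were then left out, and no expression value, fold change or p-value is reported.

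The gene identifiers, symbols and product descriptions of the table were read with pandas 2.3.3 in Python 3.11.15. Locus tags were looked up in a RefSeq gene table of Haloferax volcanii DS2 (assembly ASM2568v1), where 3882 of the 3901 genes matched. That table was used only for names and for which genes neighbour each other, and no coordinates are given because the build behind the deposited values is not named. Gene lists had been fixed before the data were examined, as patterns on the product description, and their members were counted in the table.

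The tests planned before the data were examined covered 11 comparisons between strains and doses by limma and set tests of the gene lists. They also covered a correlation of the responses of the strains and an overlap of calls between doses. The values of the deleted gene in each library were to check the labels of the knockout libraries. Genes to be named were to be taken by size of change among those past the test. None of these was run under any setting, and the deleted gene was only inspected in the unassigned columns as described above.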

Results

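The series comprised 12 RNA libraries of Haloferax volcanii, an archaeon that grows in concentrated salt. The libraries fell into 6 groups of 2, formed by 2 strains and 3 conditions. The strains were H26 and a derivative in which the gene HVO_RS06830 had been knocked out. Cultures were grown at 45 °C in rich medium to an optical density of 0.5. Sodium bisulfite, a source of sulfite, was then added to 0.1 mM or 0.5 mM for 48 h, and each strain also had untreated cultures. The labels do not say whether libraries of different groups with the same replicate number shared a batch.

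The design implied comparisons of each dose with the untreated cultures, and of the doses with each other, within a strain. It also implied comparisons of the strains at each condition, and of the response to each dose between the strains. None of these comparisons is reported, because the value columns of the deposited TPM table could not be matched by name to the samples. No statement is made on whether any gene differed between strains or doses.

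The knocked-out gene, HVO_RS06830 (older locus tag HVO_0443), was annotated in the deposited table as a DUF99 family protein, a protein family named only by a domain of unknown function. In the RefSeq gene order it was preceded by HVO_RS06825, a DUF5786 family protein, by HVO_RS06820, an MBL fold metallo-hydrolase, and by HVO_RS06815, a hypothetical protein. It was followed by HVO_RS06835, a uracil-DNA glycosylase, an enzyme class that removes uracil from DNA, and by phnE (HVO_RS06840) and phnC (HVO_RS06845), annotated as the permease and the ATP-binding protein of a phosphonate transporter. This order follows start coordinates and takes no account of strand, so it does not give positions upstream or downstream of HVO_RS06830. All 7 genes were listed as protein coding.

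The deposited table listed 3901 genes, of which 443 had a gene symbol and 922 were described only as hypothetical proteins. By product description, 16 genes matched the list for sulfur compounds, such as sulfurtransferases, and 12 the list for cysteine and methionine metabolism. The list for iron-sulfur cluster assembly had 8 genes in the table, and that for thiol redox and oxidative stress had 24. The list for the molybdenum cofactor and molybdoenzymes matched 15 genes, and that for the respiratory chain 40. The lists for ribosomal proteins and universal stress proteins matched 54 and 35. These are counts of annotated genes whose product description matched a pattern, and not of genes that changed. A match does not by itself establish that a gene has the function of its list.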

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

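No comparison between strains or doses is reported, so no setting of a test was varied, and pseudocount, filter, scaling and left-out libraries have no values here. No paired analysis was possible because the columns carry no replicate number or label that matches a sample. By choice, no replicate number or label was assigned to the columns by order or values. The sample labels also do not say whether libraries with the same replicate number shared a batch. A match of columns to samples would therefore not by itself document a pairing. The only values for which a setting was varied were the numbers of annotated genes per list. In a check chosen after seeing the data, the product patterns were matched with upper and lower case as written, and 5 of the 28 lists then held another number of genes. The list for DNA repair and replication held 17 genes in place of 28, and that for the respiratory chain 39 in place of 40. Whether the genes matched only when case was ignored belong to these functions was not checked.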
